A study of Gallus gallus with 72 samples.

How the data were processed

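RNA from chicken breast muscle was sequenced in 72 libraries from 3 breed groups (Cornish, White Plymouth Rock and their crossbred) at 4 stages: embryonic day 17 (E17) and days 1, 21 and 42 after hatch (D1, D21 and D42), with 6 libraries in each of the 12 groups. Per the labels' protocols, frozen muscle tissue was homogenised, RNA was extracted with a Promega kit and libraries were made with an Illumina TruSeq RNA kit; the birds are labelled as male. The source name speaks of muscle myofibroblasts and stands under a cell line tag, but the extraction protocol describes tissue, so the libraries were treated as whole tissue. The age label of the E17 libraries reads as embryonic years and was taken as embryonic day 17. Group, stage and replicate number were taken from the sample labels. The labels do not say that the replicates were separate birds, so every p-value here measures only the spread between these samples, which may be partly technical.

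The submitters' processing notes name cutadapt 4.4, HISAT2 2.2.1, StringTie (no version) and the build GRCg7b, without saying what each was used for; the annotation, the strand setting and any filter are not given in the sources used here. The deposited count table holds estimated counts per gene, which are whole numbers and are not normalised. Of its values from 1 to 20, 32.87% were multiples of 4, where an even spread would give 25.0%. Every one of the 12046 genes had a count above 0 in at least 36 libraries and 2.356% of values were 0. The authors also deposited 4 tables of breed comparisons, 1 per stage. Per the file headers, their columns have the names that DESeq2 gives its output, although the tool is not stated: a mean signal per gene over libraries, a log2 fold change with its standard error, a score and a p-value. In those deposited tables no p-value exceeded 0.05, and they were used only for a comparison of sign and of the number of genes listed.

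Total counts per library ran from 16673085 (crossbred D1 library 1) to 75670549, with a median of 54464688, and the second lowest library had 47478167. No pair of libraries held identical counts. Counts were analysed as deposited with edgeR 4.0.16 in R 4.3.3: TMM scaling, the filterByExpr filter with default settings, the quasi-likelihood F test (glmQLFit and glmQLFTest), and Benjamini-Hochberg adjustment with a threshold of 0.05. Every adjusted p given for a gene comes from this test unless another tool is named. Breed groups were compared within a stage in a fit of that stage's 18 libraries, and the crossbred also against the mean of both parental breeds on the log2 scale (the mid-parent value). Stage steps, averaged over the 3 breeds with equal weight, and the dependence of the purebred difference on stage were tested in a fit of all 72 libraries with 12 group means. Log2 fold changes are given as the estimate ± standard error, and levels as CPM, the counts scaled with TMM to a fixed library total, mean ± SD over 6 libraries for a breed at 1 stage and over 18 libraries for a stage.

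The comparisons, the tests, the alternatives and 26 gene lists (contractile, metabolic, growth, stress, immune and cell type marker genes) were fixed before the data were examined, as was the rule for named genes. That rule takes genes with a symbol and a mean of at least 5 CPM over the libraries of the fit. For the purebreds at each stage it takes the 4 higher and 4 lower called genes of largest fold change whose groups did not overlap; for each stage step, the 5 higher and 5 lower; for genes called in 1 direction at all 4 stages, 6; for the crossbred against the mid-parent value, 3 each way. It adds up to 4 members of a gene list per comparison, and MSTN, PAX7, MYOD1, MYOG, IGF1 and IGF2 at every stage. Some genes that the rule takes are not reported here. Lists with at least 5 tested members were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the 26 lists of a comparison; camera with an estimated correlation and fry stand beside it. fry asks only whether the members move 1 way on balance and sets the list against no other genes. Where no separate "adjusted over the list alone" count is printed, it equalled the count over all genes tested.

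DESeq2 1.42.0 was the alternative count model. Other alternatives were size factors by median of ratios, no filter on low counts, a mean of at least 1 CPM, only the groups or stages compared, all 72 libraries in 1 fit, and the replicate number as a block. Counts divided by 4, leaving out libraries in turn, and leaving out the D42 libraries numbered 3 or the shallow D1 library were added after the data had been seen. The tests were tested on simulated data with 200 changed genes and a further set of genes shifted together as a list. Counts were drawn, independently for each gene and library, from the real means and library sizes and the spread per gene that edgeR estimated. At a log2 fold change of 1, 77.6% of changed genes were called at E17 among 11661 genes, 56.1% at D1 among 11478, 81.8% at D21 among 11400, 45.5% at D42 among 11419, and 94% for the step from D21 to D42 among 11927. In the E17 simulation 4.71% of edgeR's calls and 14.6% of DESeq2's calls were false. Since the spread came from edgeR, these shares do not rank the tools on the real data. Positions are from the RefSeq annotation of GRCg7b, to which 11541 symbols were matched. Since no strand setting is given, reads of overlapping or antisense genes cannot be told apart, and members of families of near-identical copies (fast myosin heavy chains such as MYH1B, haemoglobins, BF and BLB genes, IGLL1) are uncertain as single genes. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the library checks and plots.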

Results

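Gene expression was measured by RNA sequencing in breast muscle of male broiler-type chickens from Cornish, White Plymouth Rock and crossbred groups. Cornish and White Plymouth Rock are the parental breeds of the crossbred. Each breed was sampled at E17, D1, D21 and D42, giving 12 groups of 6 libraries. Total counts averaged from 49090556 ± 16004735 (SD, n = 6, crossbred D1) to 61874781 ± 9856227 (Cornish D1), and 10429 of the 12046 genes had counts above 0 in every library. Libraries of E17, of D1 and of the later stages lay apart: component 1 of a principal component analysis held 58.1% of the variance and component 2 held 16.1%. The mean Pearson correlation of a library with the others of its group ran from 0.9133 (crossbred D42 library 3) to 0.9846.

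**Figure D1:**
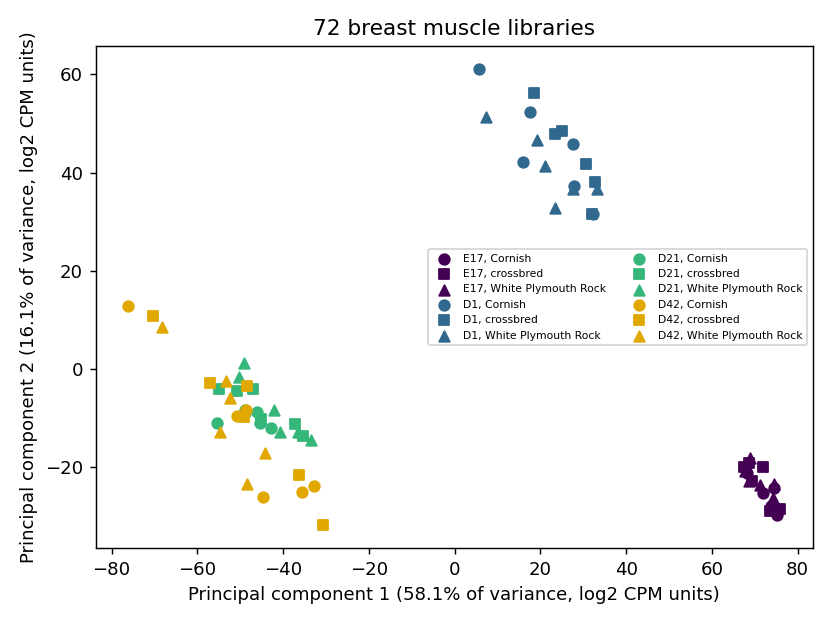
Principal component scores of the 72 libraries on log2 CPM, component 1 (58.1% of variance) on the horizontal axis and component 2 (16.1%) on the vertical axis, with 1 point per library, coloured by stage and shaped by breed. The E17 and the D1 libraries each lie apart from the other stages, the ranges of D21 and D42 overlap, and the breeds overlap within each stage.

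The first comparison asked which genes differed between the purebreds at E17. Cornish muscle had more transcript of SHANK2, a postsynaptic scaffold protein, at 11.1 ± 3.33 CPM against 2.13 ± 1.42 in White Plymouth Rock (SD, n = 6 each; log2 fold change 2.38 ± 0.50, adjusted p = 0.0165). LRRN1, a leucine-rich repeat membrane protein, was at 56.9 ± 17.3 against 19.9 ± 6.31 CPM (1.52 ± 0.24, adjusted p = 0.00281). The MHC class I gene BF2 (1.22 ± 0.20, adjusted p = 0.00364) and the haemoglobin gene HBE1 (1.22 ± 0.31, adjusted p = 0.0373) were also higher in Cornish. LRCH2 was lower in Cornish, at 30.1 ± 2.81 against 157 ± 23.5 CPM (-2.39 ± 0.20, adjusted p = 4.09e-06). CBLN1, which encodes a secreted synaptic organiser, was at 4.00 ± 2.31 against 66.1 ± 25.8 CPM (-4.05 ± 0.75, adjusted p = 0.00903). CRISPLD2 (-1.77 ± 0.31, adjusted p = 0.00626) and AHSG, the plasma glycoprotein fetuin (-1.14 ± 0.24, adjusted p = 0.0165), were lower too. For each of these 8 genes all 6 Cornish libraries lay on 1 side of all 6 White Plymouth Rock libraries. The rule that took them required this. On GRCg7b, SHANK2 spans 17479889 to 17823099 on chromosome 5, LRRN1 spans 18458125 to 18479460 on chromosome 12, LRCH2 spans 2814407 to 2854691 on chromosome 4 and CBLN1 spans 6684305 to 6687213 on chromosome 11.

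**Figure D2:**
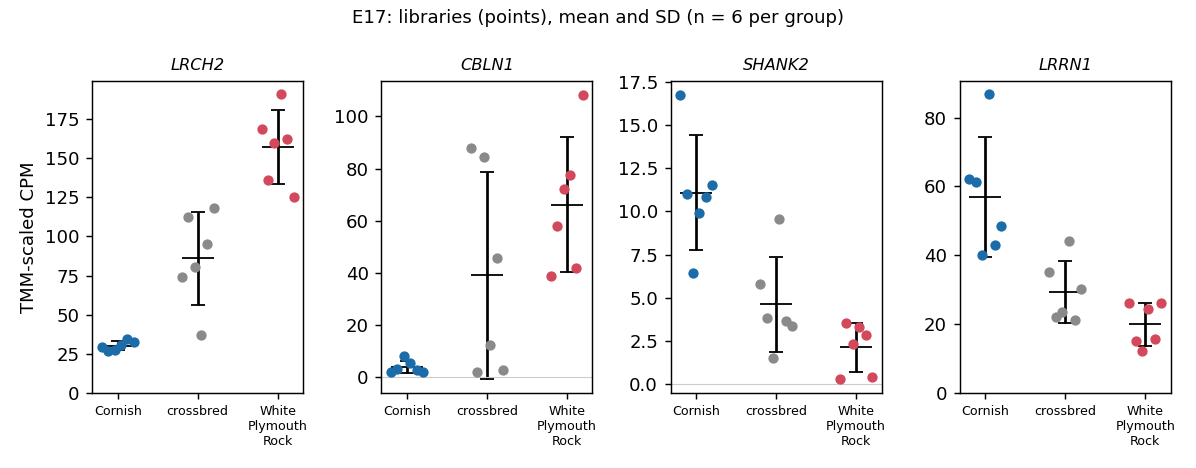
TMM-scaled CPM (vertical axes) of LRCH2, CBLN1, SHANK2 and LRRN1 at E17 in the Cornish, crossbred and White Plymouth Rock groups, with points for single libraries and bars for the mean and SD (n = 6 per group). LRCH2 averaged 30.1 CPM in Cornish, 86.1 in the crossbred and 157 in White Plymouth Rock.

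Ribosomal protein genes were lower in Cornish at E17 as a group: of 60 tested, 33 fell and 0 rose over all genes tested, and 55 fell adjusted over the list alone; without White Plymouth Rock library 5, 12 fell over all genes tested. With all libraries their median log2 fold change was -0.323, with RPS3A at -0.60 ± 0.10, RPS2 at -0.45 ± 0.08 and RPL38 at -0.42 ± 0.07 (camera, adjusted p = 1.86e-40; adjusted p = 0.381 with an estimated correlation; fry, adjusted p = 0.0265). Red blood cell genes moved the other way: 5 of 13 rose and 0 fell, and 7 rose adjusted over the list alone. Among them were HBA1 at 0.74 ± 0.18 and the anion exchanger SLC4A1 at 0.74 ± 0.18 (camera, adjusted p = 4.52e-06; adjusted p = 0.381 with an estimated correlation; fry, adjusted p = 0.0388). Among 21 endothelial markers 1 rose, CDH5 at 0.36 ± 0.09, and 8 did so adjusted over the list alone (camera, adjusted p = 1.04e-05; adjusted p = 0.514 with an estimated correlation; fry, adjusted p = 0.0566). Cell cycle genes had a median of 0.175 with 0 of 33 past the threshold (camera, adjusted p = 8.53e-05; adjusted p = 0.881 with an estimated correlation). Of 28 genes of fatty acid uptake and oxidation, 1 rose (CPT2, 0.33 ± 0.09) and 3 did adjusted over the list alone (camera, adjusted p = 0.000455; adjusted p = 0.705 with an estimated correlation). Of 22 myogenic regulators, 2 fell, EYA1 at -0.36 and LBX1 at -0.27, while 3 rose and 2 fell adjusted over the list alone (camera, adjusted p = 0.743). Of 10 skin epithelium markers 2 fell, or 1 rose and 5 fell adjusted over the list alone, with a median of -2.26 and KRT14 at -1.58 ± 0.35 (adjusted p = 0.0191; camera, adjusted p = 0.435). They were uneven between libraries: KRT13 reached 89.2 and 211 CPM in White Plymouth Rock libraries 1 and 5.

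In all, 436 of 11717 genes differed between the purebreds at E17, 193 higher and 243 lower in Cornish, and 55 of them by at least 2-fold. DESeq2 called 868 genes, and a fit of all 72 libraries called 46, in which SHANK2, HBE1 and AHSG were no longer past the threshold. The count fell to 252, 258, 252 and 249 without Cornish library 1, 4, 5 or 6.

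At D1 no gene passed the threshold between the purebreds by edgeR (0 of 11566 tested), while DESeq2 called 78. By edgeR 1002 genes had an unadjusted p under 0.05, where about 578 would if no gene differed. The genes closest to the threshold, chosen after their values were seen, were LY6E, at 147 ± 13.3 CPM in Cornish against 64.3 ± 14.9 in White Plymouth Rock (1.20 ± 0.20), and FAM181B, at 10.5 ± 1.92 against 24.3 ± 9.0 CPM (-1.20 ± 0.20). Both had an adjusted p of 0.0676. Genes of oxidative phosphorylation had a median log2 fold change of 0.203 over 75 tested, with 0 past the threshold over all genes and 1 higher adjusted over the list alone (camera, adjusted p = 5.3e-11; adjusted p = 0.764 with an estimated correlation; fry, adjusted p = 0.603). Leukocyte markers had a median of -0.425 over 29 tested, with 0 past the threshold over all genes and 1 lower adjusted over the list alone, and the cathepsin gene CTSS at -1.48 ± 0.29 (adjusted p = 0.107; camera, adjusted p = 4.97e-05; adjusted p = 0.653 with an estimated correlation). Endothelial markers had a median of 0.279 (camera, adjusted p = 5.08e-05; adjusted p = 0.764 with an estimated correlation). In the fit of all 72 libraries 120 genes passed at D1. At D1, 10.4% of genes simulated with a log2 fold change of 0.5 were called, so changes of that size were mostly not detectable.

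At D21 genes of the circadian clock were among the clearest differences between the purebreds. PER3 was at 36.5 ± 6.37 CPM in Cornish and 10.03 ± 2.31 in White Plymouth Rock (1.86 ± 0.19, adjusted p = 6.14e-05). NR1D1 (1.24 ± 0.23, adjusted p = 0.00942), NR1D2 (1.02 ± 0.18, adjusted p = 0.00683) and PER2 (1.01 ± 0.19, adjusted p = 0.00865), which act as repressors in the clock, were higher in Cornish too. NPAS2, an activator in the same loop, was lower, at 3.44 ± 0.71 against 7.80 ± 1.65 CPM (-1.18 ± 0.17, adjusted p = 0.00228). Of 15 clock genes tested 5 rose and 2 fell, and 5 rose and 4 fell adjusted over the list alone. Their median was -0.0783 and their mean 0.185, which differ in sign, and camera gave no call (adjusted p = 0.126; fry, adjusted p = 0.27).

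**Figure D3:**
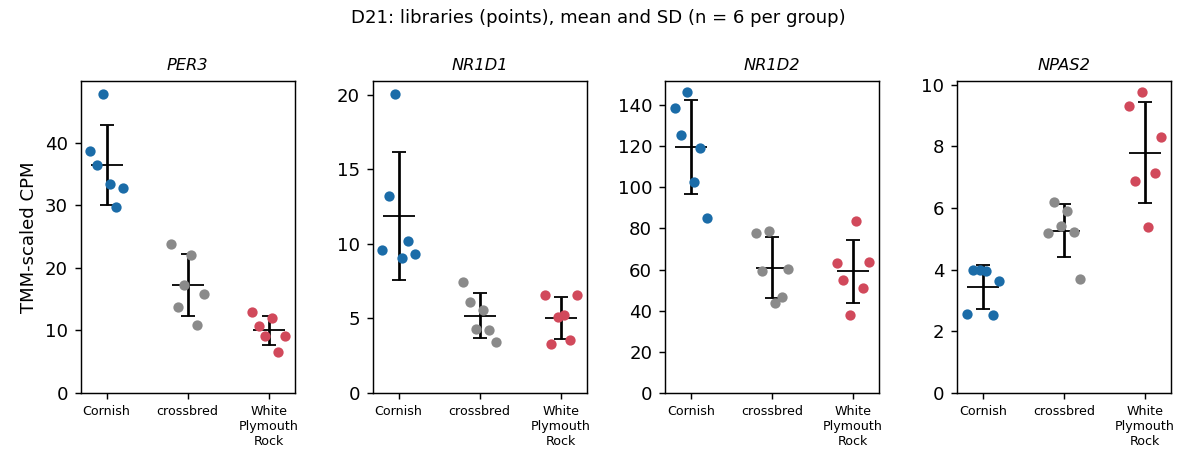
TMM-scaled CPM (vertical axes) of PER3, NR1D1, NR1D2 and NPAS2 at D21 in the Cornish, crossbred and White Plymouth Rock groups, with points for single libraries and bars for the mean and SD (n = 6 per group). PER3 averaged 36.5 CPM in Cornish, 17.2 in the crossbred and 10.03 in White Plymouth Rock, and NPAS2 ran the other way, at 3.44, 5.27 and 7.80 CPM.

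The polysialyltransferase ST8SIA2 was also higher in Cornish at D21, at 70.2 ± 34.1 against 18.4 ± 6.03 CPM (1.93 ± 0.37, adjusted p = 0.0105). ARL11 (1.72 ± 0.26, adjusted p = 0.00306) and the metalloprotease gene ADAMTS17 (1.63 ± 0.26, adjusted p = 0.005) were higher as well. EMB, which encodes the membrane glycoprotein embigin, was lower in Cornish (2.74 ± 0.52 against 9.06 ± 2.41 CPM; -1.72 ± 0.21, adjusted p = 0.000485). CETP, of cholesteryl ester transfer, was at -1.43 ± 0.25 (adjusted p = 0.00683), the prostaglandin D synthase gene PTGDS at -1.24 ± 0.23 (adjusted p = 0.0085) and KLHL25 at -1.19 ± 0.18 (adjusted p = 0.00306). These 7 genes and PER3 separated all 6 libraries of 1 purebred from all 6 of the other, as the rule that took them required. On GRCg7b, PER3 spans 279116 to 298339 on chromosome 21, ST8SIA2 spans 14513606 to 14539806 on chromosome 10, EMB spans 15273927 to 15298545 on chromosome Z and CETP spans 604343 to 609993 on chromosome 11.

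Within the insulin-like growth factor and myostatin axis 3 of 31 genes fell in Cornish at D21, and 3 adjusted over the list alone: IGFBP5 (-1.11 ± 0.17), the follistatin-like gene FSTL3 (-1.04 ± 0.24) and PIK3R1 (-0.75 ± 0.18). The list was not called by camera (adjusted p = 0.0985), and fry gave an adjusted p of 0.0303. Fast-twitch contractile genes had a median of 0.175, and of 12 tested 1 rose, the fast myosin heavy chain MYH1B (0.83 ± 0.19, adjusted p = 0.0225), with 3 adjusted over the list alone (camera, adjusted p = 0.00322; adjusted p = 0.643 with an estimated correlation). Cell cycle genes had a median of 0.401, and of 33 tested 1 rose, with 7 adjusted over the list alone (camera, adjusted p = 4.57e-09; adjusted p = 0.643 with an estimated correlation; fry, adjusted p = 0.163). Ribosomal protein genes lay above 0 at this stage, with a median of 0.183 and 1 of 60 risen, RPS28 at 0.80 ± 0.18 (camera, adjusted p = 3.12e-08; adjusted p = 0.643 with an estimated correlation). Of 26 interferon response genes 1 rose, IRF7 at 1.11 ± 0.21 (camera, adjusted p = 0.000339; adjusted p = 0.666 with an estimated correlation). Of 12 markers of smooth muscle and pericytes 1 rose, ABCC9 at 0.44 ± 0.08, and 3 did adjusted over the list alone, with a median of 0.391 (camera, adjusted p = 0.00262; adjusted p = 0.63 with an estimated correlation).

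At D21 337 of 11513 genes differed, 176 higher and 161 lower in Cornish, 87 of them by at least 2-fold. DESeq2 called 739 and a fit of all 72 libraries called 217, in which ARL11 and PTGDS were no longer past the threshold. The count fell to 186, 208 and 165 without Cornish library 1, Cornish library 2 or White Plymouth Rock library 3.

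At D42 the purebreds differed in 4 genes (2 higher and 2 lower in Cornish, 11532 tested), each with an adjusted p of 0.0452. The potassium channel gene KCNH2 was at 25.6 ± 7.63 CPM in Cornish against 11.7 ± 2.47 in White Plymouth Rock (1.13 ± 0.19), and FAM204A at 23.7 ± 5.30 against 13.9 ± 1.18 (0.77 ± 0.13). STEAP3, a metalloreductase of iron handling, was at 5.57 ± 0.56 against 11.99 ± 3.31 CPM (-1.11 ± 0.18). MPP1, which lay outside the rule for named genes and was chosen after its values were seen, was at 67.0 ± 15.0 against 144 ± 38.5 CPM (-1.10 ± 0.19). On GRCg7b, KCNH2 spans 359416 to 383826 on chromosome 2 and STEAP3 spans 28019425 to 28039574 on chromosome 7. Interferon response genes had a median log2 fold change of -0.787 over 26 tested, with 0 past the threshold over all genes and 2 lower adjusted over the list alone (camera, adjusted p = 7.78e-12; adjusted p = 0.668 with an estimated correlation; fry, adjusted p = 0.48). Ribosomal protein genes had a median of 0.297 with 0 of 60 past the threshold (camera, adjusted p = 1.09e-14; adjusted p = 0.668 with an estimated correlation). Genes of muscle atrophy and autophagy had a median of -0.406 with 0 of 25 past the threshold (camera, adjusted p = 3.87e-05; adjusted p = 0.668 with an estimated correlation).

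The libraries numbered 3 lay apart from the others in all 3 breeds at D42. In a principal component analysis of this stage alone, component 1 held 49.7% of the variance, and the loadings of library 3 were 0.496 in Cornish, 0.553 in the crossbred and 0.356 in White Plymouth Rock, against -0.295 to 0.077 for the other libraries. Relative to the other libraries of their groups, interferon response genes stood at -0.262 ± 0.683 log2 units in them (mean and SE over 3 breeds). Ribosomal protein genes stood at 0.283 ± 0.268. Gene lists were not tested without them. Without these libraries no gene passed between the purebreds by edgeR (0, with 1384 at an unadjusted p under 0.05, against 978 with all libraries). DESeq2 on all libraries called 68. With all 72 libraries in 1 fit 168 genes passed, and with only the 2 groups compared 0. The replicate number as a block also gave 0, with 1650 at an unadjusted p under 0.05. At D42 same-numbered libraries of different breeds had a mean correlation of 0.263, against -0.046 for other numbers.

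**Figure D4:**
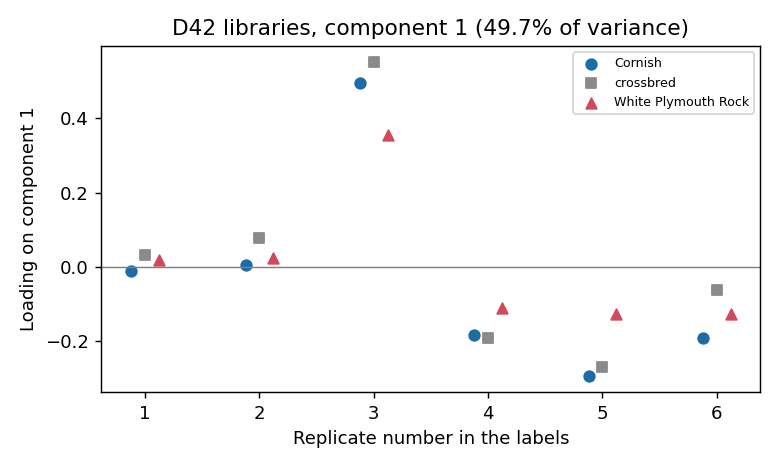
Loading on component 1 (49.7% of variance, no unit) of each D42 library, on the vertical axis, against its replicate number in the labels, on the horizontal axis, with 1 point per library and the breed shown by the marker. The libraries numbered 3 have the loadings 0.496, 0.553 and 0.356, above all others.

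Whether the purebred difference itself depended on stage was tested with an interaction term, which 32 of 11932 genes passed (1343 at an unadjusted p under 0.05; 161 by DESeq2). LRCH2 was lower in Cornish by -2.39 at E17, with log2 fold changes of -0.45, 0.20 and 0.21 at D1, D21 and D42 (adjusted p = 1.87e-12). CBLN1 went from -4.05 at E17 to 0.32, 0.40 and 0.94 (adjusted p = 0.00538). SMPX, a small muscle protein, went from -0.36 and 0.24 to 1.63 and 2.55 at D21 and D42 (adjusted p = 0.0092). The clock genes NR1D1 (0.54, -1.87, 1.24 and -0.30 over the 4 stages; adjusted p = 0.0313) and NR1D2 (-0.24, -0.54, 1.02 and -0.18; adjusted p = 0.035) also depended on stage. So did the ribosomal protein genes RPS28 (adjusted p = 0.0299) and RPL35A (adjusted p = 0.0307). SMPX, the clock genes and the ribosomal genes were chosen for this comparison after their values were seen. The term was tested in the fit of all 72 libraries, which takes 1 spread per gene over the 4 stages. That fit called 46, 120, 217 and 168 purebred differences at E17, D1, D21 and D42, against 436, 0, 337 and 4 in fits per stage. Stage dependence that rests on D1 or D42 is therefore less certain.

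The crossbred was compared with each parent and with the mid-parent value. At E17 it had more LRCH2 than Cornish (1.52 ± 0.19, adjusted p = 0.00322), at 86.1 ± 29.8 CPM, and more HACD4, a gene of fatty acid elongation (5.84 ± 0.97 against 3.17 ± 0.65 CPM; 0.88 ± 0.14, adjusted p = 0.0437). These were the 2 genes called of 11717, and with only the 2 groups compared 0 passed; DESeq2 called 50. Against White Plymouth Rock the only gene called at E17 was CD1C, chosen after its values were seen, at 0.284 ± 0.11 CPM in the crossbred and 0 in every White Plymouth Rock library; DESeq2 called 83. With a mean of at least 1 CPM or with counts divided by 4, 0 genes passed, and with only the 2 groups compared 1 gene passed, which was not CD1C. At D21 the crossbred differed from Cornish in 14 genes, 3 higher and 11 lower, all with an adjusted p of 0.0489. They included lower PER3 (-1.08 ± 0.18), NR1D1 (-1.20 ± 0.23), NR1D2 (-0.97 ± 0.18), the CNTF receptor gene CNTFR (-1.61 ± 0.31) and the calpain gene CAPN2 (-0.85), and higher LRRC30, at 14.3 ± 4.61 against 2.93 ± 1.49 CPM (2.29). DESeq2 called 127, and with only the 2 groups compared or with no filter on low counts 0 passed.

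Against Cornish, edgeR called 0 genes at D1 and 0 at D42 (674 and 240 at an unadjusted p under 0.05; 15 and 1 by DESeq2). Against White Plymouth Rock it called 0 at D1, D21 and D42 (663, 539 and 580 unadjusted, and 7, 12 and 16 by DESeq2). With the replicate number as a block it called 0 against Cornish and 0 against White Plymouth Rock at D42, with 547 and 1001 unadjusted. Against the mid-parent value edgeR called 0 at each of the 4 stages (671, 570, 389 and 248 unadjusted, and 2, 4, 3 and 0 by DESeq2). With all 72 libraries in 1 fit it called 1, 24, 0 and 11. If no gene differed, about 586, 578, 576 and 577 genes would fall under 0.05 in each comparison at E17, D1, D21 and D42. The unadjusted counts against the mid-parent value lay below this at D1, D21 and D42. Among the crossbred comparisons the smallest camera p was that of ribosomal protein genes at E17, which had a median of 0.193 over Cornish. Over all genes 0 of 60 members passed, and 8 were higher adjusted over the list alone (camera, adjusted p = 7.63e-23; adjusted p = 0.582 with an estimated correlation; fry, adjusted p = 0.201). Against the mid-parent value at D1 ribosomal protein genes had a median of 0.156 (camera, adjusted p = 7.15e-14) and genes of oxidative phosphorylation -0.178 (camera, adjusted p = 8.01e-12), each with 0 members past the threshold and an adjusted p = 0.466 with an estimated correlation.

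From E17 to D1, across the breeds, genes of mitochondrial energy supply rose. UCP3, a mitochondrial carrier, went from 0.368 ± 0.232 to 73.5 ± 51.8 CPM (SD, n = 18 each; 7.58 ± 0.29, adjusted p = 6.33e-33). ASB4 (6.41 ± 0.22), the muscle chloride channel CLCN1 (5.85 ± 0.19), KLHL38 (5.74) and the small heat shock protein HSPB7 (5.51 ± 0.41) rose with it. FAM81A (-6.50 ± 0.35), EFHD2 (-6.19), cardiac troponin T TNNT2 (-5.31 ± 0.36; 540 ± 196 to 13.7 ± 11.7 CPM), SDR42E2 (-5.29) and the nociceptin precursor PNOC (-5.00) fell. Genes of oxidative phosphorylation rose in 70 of 75 cases and fell in 1, with a median of 1.11 and COX5A at 1.54 ± 0.07 (camera, adjusted p = 1.07e-30; adjusted p = 0.129 with an estimated correlation; fry, adjusted p = 2.96e-22). Of 28 genes of fatty acid uptake and oxidation 23 rose and 2 fell, with HADHB at 2.56 ± 0.10 (camera, adjusted p = 5.2e-12; adjusted p = 0.0522 with an estimated correlation). Of 27 glycolytic genes 19 rose and 6 fell, with LDHA at 3.65 ± 0.17 (camera, adjusted p = 5.39e-05; adjusted p = 0.18 with an estimated correlation). Clock genes rose in 12 of 15 cases and fell in 1, with NR1D1 at 4.98 ± 0.31 (camera, adjusted p = 0.000514; adjusted p = 0.0904 with an estimated correlation).

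Cell cycle genes fell over the same step in 32 of 33 cases, with a median of -1.31 (camera, adjusted p = 3.45e-05; adjusted p = 0.519 with an estimated correlation; fry, adjusted p = 1.31e-08). Collagen and other matrix genes fell in 31 of 36 cases and rose in 4, with COL14A1 at -4.93 ± 0.29 and SPARC at -1.91 ± 0.13 (camera, adjusted p = 1.1e-06; adjusted p = 0.519 with an estimated correlation). Developmental and cardiac-type muscle isoforms fell in 11 of 16 cases and rose in 1 (camera, adjusted p = 0.000487; adjusted p = 0.129 with an estimated correlation). In all 8705 of 11932 genes changed, 4456 up and 4249 down, 2698 of them by at least 2-fold.

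From D1 to D21 genes of immune cells and of the interferon response rose. Immunoglobulin IGLL1 went from 0.146 ± 0.189 to 163 ± 117 CPM (10.27 ± 0.63, adjusted p = 1.01e-22). It was followed by JCHAIN (9.11 ± 0.66), the interferon-induced MX1 (8.31 ± 0.76), gga-mir-12268 (6.89) and RPL3L, the muscle paralogue of RPL3 (6.60 ± 0.30; 11.4 ± 14.0 to 1025 ± 223 CPM). The light chain gene MYL3 (-9.42 ± 1.02), C8orf22 (-8.48), STK17A (-6.26), the transsulfuration enzyme gene CBS (-6.10 ± 0.23; 276 ± 133 to 3.97 ± 1.19 CPM) and WFIKKN1, whose product binds myostatin (-5.80 ± 0.34), fell. Of 30 leukocyte markers 27 rose and 1 fell, with CD74 at 4.66 ± 0.18 (camera, adjusted p = 6.61e-14; adjusted p = 0.108 with an estimated correlation). Of 26 interferon response genes 25 rose, with B2M at 3.19 ± 0.10 and TLR3 at 3.63 ± 0.22 (camera, adjusted p = 1.19e-10; adjusted p = 0.37 with an estimated correlation).

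Glycolytic genes rose from D1 to D21 in 22 of 27 cases and fell in 4, with GAPDH at 2.96 ± 0.12 and GPI at 3.52 ± 0.15 (camera, adjusted p = 2.49e-13), a call that held with an estimated correlation (adjusted p = 0.00914). Genes of fatty acid uptake and oxidation fell in 21 of 28 cases and rose in 1, or in 2 adjusted over the list alone, with ETFA at -2.80 ± 0.10 and HADHB at -2.31 ± 0.10 (camera, adjusted p = 1.58e-12). This call also held (adjusted p = 0.0267 with an estimated correlation). Markers of nerve and Schwann cells fell in 11 of 16 cases and rose in 1, with FOXD3 at -3.70 ± 0.15 and SOX10 at -2.77 ± 0.17 (camera, adjusted p = 7.82e-05; adjusted p = 0.0968 with an estimated correlation). Oxidative phosphorylation genes fell in 50 of 75 cases and rose in 11 (camera, adjusted p = 0.00124; adjusted p = 0.966 with an estimated correlation). Fast-twitch contractile genes rose in 9 of 12 cases and fell in 1 (camera, adjusted p = 0.00642; adjusted p = 0.704 with an estimated correlation). Slow-twitch genes had a median of -3.22, with 3 risen and 11 fallen of 14, and were not called by camera (adjusted p = 0.418). In all 8735 genes changed, 4349 up and 4386 down, 2669 by at least 2-fold.

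From D21 to D42 the growth factor gene GDF3 (1.15 ± 0.12), NAAA (0.75), ADSS2 (0.62) and CTCF (0.37) rose. FDPS, a gene of sterol synthesis, fell (-1.38 ± 0.10; 94.8 ± 20.8 to 36.5 ± 10 CPM). The basement membrane collagen COL4A5 (-1.51), PPDPF (-1.44) and MATN2 (-1.34) fell as well. Interferon response genes rose in 25 of 26 cases, with B2M at 1.03 ± 0.10 (camera, adjusted p = 1.01e-15; adjusted p = 0.244 with an estimated correlation; fry, adjusted p = 1.39e-05). Leukocyte markers rose in 21 of 30 cases, or 24 adjusted over the list alone, with 2 fallen (camera, adjusted p = 2.98e-06; adjusted p = 0.653 with an estimated correlation). Red blood cell genes fell in 10 of 13 cases, with HBAD at -1.85 ± 0.28 (camera, adjusted p = 9.45e-10), and this call held with an estimated correlation (adjusted p = 0.0499). Cell cycle genes fell in 14 of 33 cases (camera, adjusted p = 4.27e-05; adjusted p = 0.653 with an estimated correlation). Endothelial markers fell in 8 of 21, or 11 adjusted over the list alone (camera, adjusted p = 0.000191; adjusted p = 0.653 with an estimated correlation). In the D42 libraries numbered 3 the median difference from the other libraries of the group was -1.48 ± 0.249 log2 units for endothelial markers, -1.68 ± 0.289 for leukocyte markers, -1.42 ± 0.46 for cell cycle genes and -0.509 ± 0.119 for red blood cell genes (mean and SE over 3 breeds). In all 3893 of 11932 genes changed, 2036 up and 1857 down, 482 by at least 2-fold, and 3607 passed without these libraries.

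**Figure D5:**
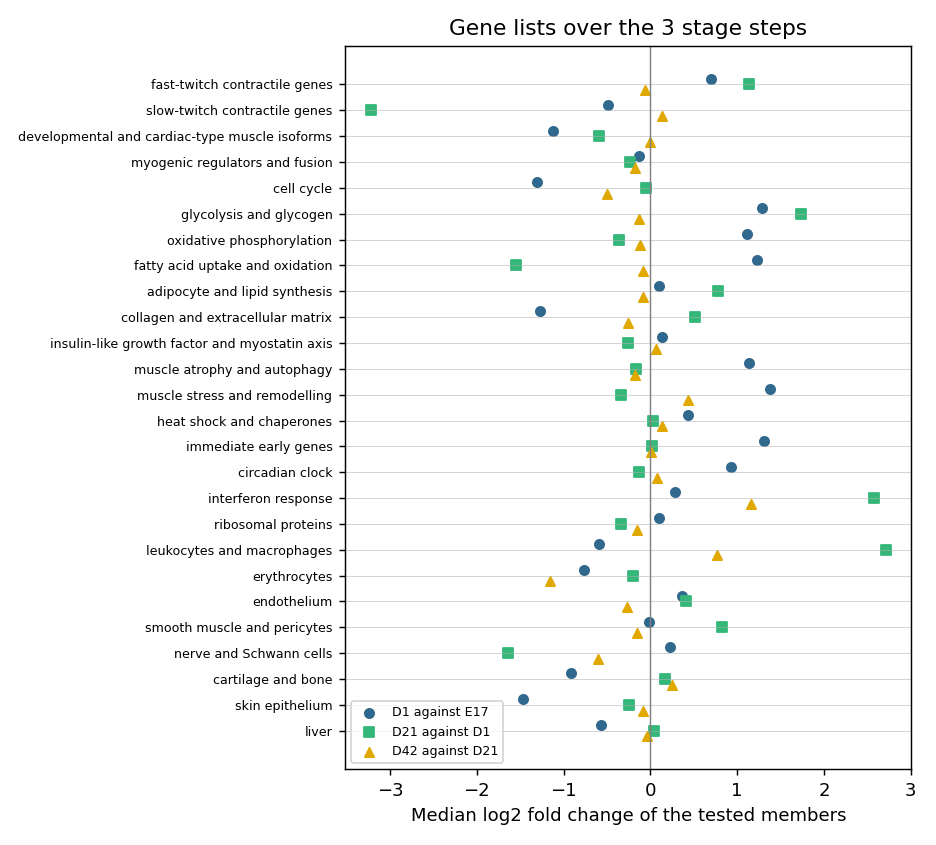
Median log2 fold change of the tested members of 26 gene lists (horizontal axis, log2 units) in the steps from E17 to D1, D1 to D21 and D21 to D42, with 1 point per list and step and the lists named on the vertical axis. Genes of fatty acid uptake and oxidation stand at 1.23 in the first step and -1.55 in the second, and interferon response genes at 2.57 and 1.16 in the second and the third steps.

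None of the 6 growth and myogenic regulators fixed in advance passed the threshold between the purebreds at any stage. Myostatin, MSTN, which limits muscle growth, had log2 fold changes of -0.19 ± 0.26, 0.40 ± 0.40, -0.24 ± 0.29 and -0.17 ± 0.39 at E17, D1, D21 and D42 (adjusted p = 0.734, 0.819, 0.714 and 0.949). IGF1 had 0.04 ± 0.16, -0.10 ± 0.73, 0.37 ± 0.24 and 0.19 ± 0.43 (adjusted p = 0.93, 0.977, 0.449 and 0.946), and averaged 1.14 CPM at D1. With errors of this size, the lack of a call does not show that the breeds were alike. The lowest adjusted p was 0.217 for IGF2 at E17 (0.32), shared by the satellite cell gene PAX7 (-0.20). The myogenic factor MYOD1 was closest at D21 (0.74, adjusted p = 0.237), while MYOG had an adjusted p of 0.482 or above at the 4 stages. Between stages MSTN fell from 156 ± 50.1 to 8.71 ± 5.25 CPM by D1 (-4.17 ± 0.24, adjusted p = 2.96e-24) and rose to 66.3 ± 23.4 CPM at D21 (2.93 ± 0.23). IGF1 fell by 2.41 on the log2 scale and rose by 1.84 in the same steps, MYOG fell by 2.06 and rose by 1.49, and MYOD1 rose by 1.46 and fell by 0.70. PAX7 fell in each of the 3 steps (-0.81, -0.36 and -0.28). IGF2 rose by 0.33 from E17 to D1 and fell by 0.38 from D21 to D42, with 0.20 in the step between (adjusted p = 0.132).

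No gene was called between the purebreds in 1 direction at all 4 stages, so the rule named none there. With 0 calls at D1 none could be, so this says nothing of whether differences persist. The table held 4 symbols of the W chromosome, which gave no check of the male label. UBAP2L2 and ENS-1 reached at most 1.70 and 1.46 CPM, and MBD2 and NEDD4L were at 34.7 and 61.4 CPM or above in every library. UBAP2L2 differed between the purebreds at D21, at 0.003088 CPM in Cornish against 0.1732 in White Plymouth Rock (-5.00 ± 1.02, adjusted p = 0.0149), and was higher in the crossbred than in Cornish (5.26 ± 1.01, adjusted p = 0.0489). Over 427 Z-linked genes the level relative to autosomal genes, set against the median library of the stage, ran from -0.099 to 0.123 log2 units over the 72 libraries.

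The authors' deposited tables listed 2517, 1114, 2125 and 1203 genes between Cornish and White Plymouth Rock at E17, D1, D21 and D42. For the crossbred against Cornish the authors' deposited tables listed 1425, 965, 1320 and 301 genes, and against White Plymouth Rock 1095, 696, 666 and 712. All were listed at an unadjusted p of at most 0.05. Of the 14139 entries in the authors' deposited tables, 14090 were in the count table, and in all 14090 the sign was opposite to that of the first-named group minus the second in the counts.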

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

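The tests of stage dependence were planned for genes taken by fold change, and list members were added after the results were seen. Every group of 6 libraries behind a named gene or a total count was looked at for a library far from the rest, with no further test. The purebred difference depended on stage for 9 of the genes taken by fold change or as list members in the purebred comparisons. By fold change these were LRCH2 (adjusted p = 1.87e-12), CBLN1 (adjusted p = 0.00538), EMB (adjusted p = 0.0374) and ARL11 (adjusted p = 0.0498). The log2 fold changes at E17, D1, D21 and D42 were -2.39, -0.45, 0.20 and 0.21 for LRCH2, and -4.05, 0.32, 0.40 and 0.94 for CBLN1. For EMB they were -0.35, -1.07, -1.72 and -0.02, and ARL11 went from -1.80 at E17 to 1.72 at D21. The list members were the clock genes NR1D1 (adjusted p = 0.0313; 0.54, -1.87, 1.24 and -0.30 at the 4 stages), NR1D2 (adjusted p = 0.035; -0.24, -0.54, 1.02 and -0.18) and BHLHE41 (adjusted p = 0.0442; -0.28, -0.62, 0.54 and 0.42). The ribosomal protein genes were RPS28 (adjusted p = 0.0299; -0.37, 0.06, 0.80 and 0.81) and RPL35A (adjusted p = 0.0307; -0.35, 0.06, 0.44 and 0.70).

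Of 69 groups looked at, 6 held a library far from the rest, where chance gives about 1 in 20. The crossbred D1 group held the shallowest library, at 16673085 counts against 52959628 for the next lowest. One Cornish E17 library had BF2 at 63.3 CPM, with the next highest at 40.3. A White Plymouth Rock E17 library had CRISPLD2 at 15.4 CPM against 8.96 for the next. ST8SIA2 reached 117 CPM in 1 crossbred D21 library against 53 for the next. KLHL25 reached 40.2 CPM in a White Plymouth Rock D21 library, with the next at 24.4. STEAP3 reached 18.3 CPM in a White Plymouth Rock D42 library, with the next at 12.3.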

How the results depend on the processing

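Causes of the changes in counts were not tested unless stated. Counts divided by 4, leaving libraries out in turn and leaving out the D42 libraries numbered 3 or the shallow D1 library were chosen after seeing the data. In the order E17, D1, D21, D42, DESeq2 called 868, 78, 739 and 68 genes between the purebreds (436, 0, 337 and 4 by edgeR). It called 50, 15, 127 and 1 for the crossbred against Cornish (2, 0, 14 and 0) and 83, 7, 12 and 16 against White Plymouth Rock (1, 0, 0 and 0). Against the mid-parent value it called 2, 4, 3 and 0 (0 at each by edgeR), and it called 161 stage-dependent genes (32 by edgeR). All 72 libraries in 1 fit gave 46, 120, 217 and 168 between the purebreds and 4, 21, 17 and 1 against Cornish. The same fit gave 7, 19, 2 and 22 against White Plymouth Rock and 1, 24, 0 and 11 against the mid-parent value. Only the 2 groups compared gave 0 against Cornish at E17 and at D21, and 2 and 0 between the purebreds at D1 and D42. No filter gave 1 against the mid-parent value at E17 and 0 against Cornish at D21. A mean of at least 1 CPM and counts divided by 4 each gave 0 against White Plymouth Rock at E17, where the gene called, CD1C, is too low to be tested. With only the 2 groups compared 1 gene was called there, which was not CD1C. The purebred count at D1 was 1 without crossbred library 1, and at D42 it was 0 without the libraries numbered 3. Leaving out 1 purebred library at a time gave 249 to 418 genes at E17, with 252, 258, 252 and 249 without Cornish library 1, 4, 5 and 6. It gave 165 to 356 at D21, with 186 and 208 without Cornish library 1 and 2 and 165 without White Plymouth Rock library 3. IGF1 at E17, never past the threshold, ran from -0.05151 to 0.1011 in these fits. It changed sign without Cornish library 3 (-0.04048), Cornish library 5 (-0.05151) and White Plymouth Rock library 2 (-0.004346). The share of calls higher in the crossbred than in Cornish was 100% at E17 (64.0% by DESeq2) and 21.4% at D21 (49.6% by DESeq2). Against White Plymouth Rock at E17 it was 100% (42.2% by DESeq2 and 14.3% with all 72 libraries in 1 fit). Of 494 gene list tests 147 passed, 69 up and 78 down, and 3 did with an estimated correlation. Each stage step kept its count within 1.5 times under every alternative run. The balance of the step from D21 to D42, 2036 up and 1857 down, was less even under some alternatives: 2269 and 1645 with size factors by median of ratios, 2354 and 1751 by DESeq2, 2393 and 1555 with no filter, 2066 and 1541 without the libraries numbered 3, and 1848 and 1521 with only the stages compared. With a mean of at least 1 CPM it was 1984 and 1785. Of 63 called named genes 40 passed under every alternative fixed in advance. These 40 included every named gene of the stage steps. None of the named genes called at D42 or for the crossbred against Cornish passed under all of them. SHANK2, HBE1 and AHSG at E17 and ARL11 and PTGDS at D21 did not either. Leaving out libraries against the male label was not run, since no library was found to be against it. The replicate numbers were not taken to pair the samples, since at no stage was every same-numbered pair correlated over 0.1. At D42, however, the mean correlation between breeds was positive for every number, from 0.031 (number 1) to 0.72 (number 3). The D42 fits without the replicate block took no account of this, and the D42 gene list tests given above came from such a fit. With the block, genes at an unadjusted p under 0.05 at D42 rose from 978 to 1650 between the purebreds. They rose from 240 to 547 for the crossbred against Cornish and from 580 to 1001 against White Plymouth Rock. Libraries of different breeds with unlike numbers had mean correlations of -0.004, 0.005, -0.001 and -0.046 over the 4 stages. Those with the same number had 0.02, -0.008, 0.001 and 0.263. They were over 0.1 in 6, 5, 3 and 12 of 18 pairs, at D42 in all pairs of number 3 (0.683 to 0.771) and number 4 (0.228 to 0.342), and 4, 5, 4 and 5 of 18 libraries correlated best with their own number. With the replicate block edgeR called 313, 2, 257 and 0 genes between the purebreds, 6 and 1 against Cornish at E17 and D21, and 0 against White Plymouth Rock at E17, with 155 list tests. At D1 the block turned the sign of MYOD1 (0.007155), MYOG (0.1953) and IGF1 (0.2047), none of them past the threshold either way. At a log2 fold change of 0.5 the simulations recovered 61.2% of changed genes at E17, 10.4% at D1, 41.5% at D21 and 16.4% at D42, and at 2 they recovered 86.4% at D1 and 75.4% at D42. Few calls at D1 and D42 therefore say little of differences of 0.5, while most of those of 2 were recovered in simulation. The simulated libraries shared no structure like that of the D42 libraries numbered 3, so the D42 shares may not hold for the real libraries. The shallowest library was crossbred D1 library 1.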

Other observations

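From E17 to D1 genes of muscle atrophy and autophagy rose, 20 of 25 with 2 fallen, or 3 fallen adjusted over the list alone. Their median was 1.14 (camera, adjusted p = 5.9e-05; adjusted p = 0.264 with an estimated correlation). The transcription factor gene CEBPD went from 11.2 ± 2.7 to 312 ± 220 CPM (SD, n = 18 each; 4.78 ± 0.34), and the autophagy genes MAP1LC3A (2.38 ± 0.15), SQSTM1 (2.01 ± 0.15) and ULK1 (1.93 ± 0.14) rose too. Immediate early genes rose in 15 of 21 cases and fell in 1, with DUSP1 at 2.49 ± 0.17 (camera, adjusted p = 0.0111; adjusted p = 0.519 with an estimated correlation). Genes of muscle stress and remodelling rose in 11 of 16 cases and fell in 2, among them PLN, the regulator of the calcium pump, at 3.88 ± 0.32 (camera, adjusted p = 0.0225; adjusted p = 0.519 with an estimated correlation). Fast-twitch contractile genes rose in 10 of 12 cases and fell in 1 (camera, adjusted p = 0.0091; adjusted p = 0.519 with an estimated correlation). Lists not called by camera in this step were heat shock (15 risen and 4 fallen of 27, adjusted p = 0.0688), adipocyte (7 and 5 of 20, adjusted p = 0.332) and cartilage and bone (1 and 9 of 17, adjusted p = 0.125). The skin epithelium (0 and 7 of 10, adjusted p = 0.173) and liver lists (2 and 5 of 9, adjusted p = 0.278) were not called either. From D1 to D21 ribosomal protein genes fell in 41 of 60 cases and rose in 7 (camera, adjusted p = 0.00609; adjusted p = 0.966 with an estimated correlation). The insulin-like growth factor and myostatin axis fell in 17 of 32 cases and rose in 5, with IGFBP2 at -1.87 ± 0.14 (camera, adjusted p = 0.0116; adjusted p = 0.0641 with an estimated correlation).

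From D21 to D42 markers of nerve and Schwann cells fell in 8 of 16 cases, with FOXD3 at -1.25 ± 0.14 (camera, adjusted p = 1.68e-05; adjusted p = 0.109 with an estimated correlation). Matrix genes fell in 10 of 36 cases, with the basement membrane collagens COL4A1 and COL4A2 at -0.84 ± 0.12 and -0.85 ± 0.12 (camera, adjusted p = 4.97e-05; adjusted p = 0.653 with an estimated correlation). Both lists were also lower in the D42 libraries numbered 3 than in the other libraries of their groups, by the values given with those libraries. Ribosomal protein genes fell in 29 of 60 cases (camera, adjusted p = 2.67e-06; adjusted p = 0.653 with an estimated correlation). Oxidative phosphorylation genes fell in 25 of 75 cases and rose in 1 (camera, adjusted p = 0.00042; adjusted p = 0.662 with an estimated correlation). Glycolytic genes fell in 8 of 27 cases (camera, adjusted p = 0.0123; adjusted p = 0.653 with an estimated correlation). Heat shock genes rose in 12 of 27 cases and fell in 2, with HSPA2 at 0.87 ± 0.15 (camera, adjusted p = 0.0108; adjusted p = 0.653 with an estimated correlation). Genes of muscle stress and remodelling rose in 7 of 16 cases and fell in 2, with MUSTN1 at 1.32 ± 0.29 (camera, adjusted p = 0.0491; adjusted p = 0.653 with an estimated correlation). This list was 0.651 ± 0.0867 higher in the D42 libraries numbered 3 than in the others of their groups (SE over 3 breeds).

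The breed differences called at E17 and at D21 overlapped, although no library is shared between the stages. Of 11378 genes tested at both, 13 were higher in Cornish at both stages and 16 lower, where independent lists would share 2.92 and 3.38, and 2 went opposite ways. Genes with an unadjusted p under 0.05 and 1 direction at all 4 stages numbered 33, where the product of the rates gives 0.38. After adjustment 0 were called at all 4, which the 0 calls at D1 had already fixed. Among them was CETP, of cholesteryl ester transfer, at -1.04, -1.27, -1.43 and -1.40 over E17, D1, D21 and D42 (adjusted p = 0.0025, 0.297, 0.00683 and 0.229). The prolactin receptor gene PRLR was at -1.43, -1.23, -1.16 and -1.06 (adjusted p = 0.00186, 0.107, 0.0206 and 0.308). Both were chosen after their values were seen.

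CBLN1 was uneven within the crossbred at E17: the 6 libraries lay at 87.9, 2.11, 84.3, 12.3, 45.7 and 2.92 CPM, while Cornish ran from 2.203 to 7.999 and White Plymouth Rock from 38.9 to 108. For 412 of the 436 genes called between the purebreds at E17 the crossbred mean lay between the parents, with a median position of 0.475 from White Plymouth Rock at 0 to Cornish at 1. At D21 this held for 311 of 337 genes, with a median position of 0.377. Genes picked for a large purebred difference also bracket a group with no effect of its own, so these shares are only a description. Fast myosin heavy chains changed level with age: MYH1B averaged 30620 CPM at D21 and 7487 at D42, and MYH1C averaged 17830 at E17 and 2569 at D21. These genes are near-identical copies, so single-gene values are uncertain.

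In the weighings that follow, the tests of cell makeup at D42, of time of day and of a constant breed difference in clock genes, and of short-transcript bias were chosen after the result was seen. The demand that the list compared in the last of these be of like abundance was added later still, after its level was seen. The tests of gene length, of blood and of White Plymouth Rock library 5 were chosen before.

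The first pattern is library 3 of each breed at D42, whose mutual correlations averaged 0.72. A candidate explanation is that less tissue other than muscle fibre was taken: relative to the other libraries of their groups, leukocyte markers were at -1.68 ± 0.289, endothelium at -1.48 ± 0.249, matrix at -1.38 ± 0.229, pericytes at -1.21 ± 0.224 and nerve at -0.716 ± 0.277 (SE over 3 breeds). Fast-twitch genes were 0.804 ± 0.0757 higher. Gene length bias cannot be told apart, since Spearman's rho across genes with gene span was -0.154 in Cornish, 0.0017 in the crossbred and -0.122 in White Plymouth Rock, against -0.0621 to 0.163 in other libraries; genes are not independent replicates. The labels name no batch, and a shared batch or shared birds' history behind the number 3 stays open and untested.

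The second pattern is the clock at D21. A score of ARNTL, CLOCK, NPAS2 and NFIL3 minus PER2, PER3, NR1D1 and NR1D2 was -1.27 ± 0.271 in Cornish, 0.0834 ± 0.399 in the crossbred and 0.634 ± 0.36 in White Plymouth Rock (SD, n = 6 each), a purebred difference of -1.9 ± 0.184 (exact permutation test, two-sided, p = 0.00216, the smallest its 924 splits give; Benjamini-Hochberg adjusted p = 0.00864 over 4 stages). That is consistent with the breeds having been sampled at different times of day, as a hypothesis found and tested on the same data. A breed difference in clock level at every stage cannot be told apart, since a difference in sampling time would mix hour with level at each stage. The difference at D1 went the other way, at 0.626 ± 0.275, but did not pass after adjustment (exact permutation test, p = 0.0433, adjusted p = 0.0866). At E17 it had the sign of D21, at -0.182 ± 0.107 (exact permutation test, p = 0.0974, adjusted p = 0.13). At D42 it was 0.281 ± 0.468 (exact permutation test, p = 0.554). A difference as large as that at D21 was not seen at the other stages. A breed difference in clock phase that starts by D21 stays open, as untested.

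The third pattern is the lower ribosomal protein genes of Cornish at E17, with a median of -0.323. The purebred difference in the mean log2 CPM of the list per library had an SE of 0.0701 (n = 6 per group). A bias against short, abundant transcripts cannot be told apart. The oxidative phosphorylation list had a median of -0.00104 (SE of its mean score 0.0669), but its median level was 57.1 CPM against 452. Of its members 38 of 75 lay below 0 (SD over members 0.192), with NDUFA6 (-0.35 ± 0.09) and SDHAF4 (-0.63 ± 0.17) called lower. White Plymouth Rock library 5, with epithelial transcripts, is not the source alone, since without it the median was -0.283 and 12 members were still called. Blood in the Cornish samples cannot be told apart, because within groups the ribosomal score and the score of 4 haemoglobin genes had r = -0.156 (permutation p = 0.583) and rho = -0.135 (permutation p = 0.629) over 18 libraries, and r = -0.117 without the 2 farthest. A breed difference in ribosome production or in developmental timing stays open, as untested.

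Regrouping the libraries of a stage at random, 100 splits with the real one included, tested whether chance can be excluded for each count. Between the purebreds chance in the grouping of these libraries was excluded at E17 (436 genes, highest other 1, 1 split as large) and D21 (337, highest other 14, 1 split). Because all 3 breeds were mixed, this covers only the case in which no breed differs. No split can speak of chance between birds, since the labels do not say that the replicates were separate birds. At D42 (4, highest other 11, 2 splits) few splits were as large, but they took no account of how the libraries numbered 3 lie together. The 4 calls became 0 without those libraries, 0 with the replicate block and 0 with only the 2 groups compared, so chance was not taken as excluded. Without those libraries the genes at an unadjusted p under 0.05 nonetheless rose from 978 to 1384. For the crossbred against Cornish at D21 (14, highest other 1, 1 split) no other split came near the count. The splits mixed all 3 breeds, and the purebreds differed in 337 genes, which widens the spread within the mixed groups. They therefore cannot exclude chance for this pair. In this comparison 0 passed with only the 2 groups compared or with no filter on low counts, and no splits were run in those fits. Against Cornish at E17 (2, highest other 4, 3 splits) and White Plymouth Rock at E17 (1, highest other 1, 3 splits) few splits were as large, but other splits reached these counts. The 2 calls became 0 with only the 2 groups compared, and the 1 call, CD1C, was lost there, with a mean of at least 1 CPM and with counts divided by 4. Chance was therefore not taken as excluded for either. With a real count of 0 all 100 splits are as large by construction, so they say nothing of chance for the purebreds at D1 (highest other 2) or the crossbred against Cornish at D1 (2) and D42 (1117). The same held against White Plymouth Rock at D1 (3), D21 (162) and D42 (1), and against the mid-parent value (20, 2, 41 and 1 at the 4 stages). The splits with 1117 and 11 genes at D42, 162 and 41 at D21 and 20 at E17 came from a few regroupings and point to a structure of the samples, which was not tested at E17 and D21. With 30 splits each, 1 split, the real one, was as large for the steps from E17 to D1 (8705, highest other 56), D1 to D21 (8735, highest other 3407) and D21 to D42 (3893, highest other 300). Chance was excluded for the counts of these steps. For stage dependence the real split alone was also as large (32, highest other 3). Those splits exchanged the purebred labels within each stage, which removes every breed difference, also one constant over the stages. They therefore cannot exclude chance for dependence on stage where breed differences are real.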
